A study of Danio rerio with 8 samples.

How the data were processed

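RNA was extracted from GFP-positive cells that were sorted from dissociated larvae at 6 days post fertilization, and libraries were made from polyadenylated RNA with a SMART-Seq v4 low-input kit, per the labels' protocols. Larvae had been scored as mutant or wild type by confocal microscopy on earlier days. The labels name the libraries biological replicates and do not say how many larvae or clutches each held.

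The deposited table gives raw read counts per Ensembl gene for 8 libraries. HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0 and the genome build GRCz11 are named in the submitters' processing notes, without their roles, and the strand setting is not given in the sources used here. The table also holds 16 columns of other per-library values, which were not used here. Only the counts were tested. Gene lengths from the table served in a check of length bias.

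Columns of the table were assigned to a genotype by their names. Their numbers, 1, 2, 4 and 5, differ from the numbers in the sample titles, so no column was tied to a single titled sample, and libraries carry the column numbers here. Chi-square per degree of freedom between libraries of a genotype lay between 50.1 and 104.7, so no library was a repeat sequencing of another. The measure allows for counting noise only, so it cannot exclude libraries prepared separately from the same RNA. Libraries with the same column number deviated together from their genotype means (correlations of 0.124 to 0.288 across genes, against -0.182 to -0.00667 for different numbers). Each number was therefore taken to pair a mutant with a sibling library. The main test, set before this check, and the exact permutation tests leave the pairing out. A fit with replicate number as a block was run beside the main test. The pairing comes from the column names and this check, not from the labels.

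Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr at a minimum count of 10, which kept 16086 of 24221. Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood test without covariates, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values were computed on the TMM-scaled library size. Fold changes are mutant over sibling, and p-values measure the spread among these libraries only.

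Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over 32 lists. Of these, 18 described functions of the cells and 14 served as checks, 12 of them for markers of other cell types. The design, the lists, the thresholds, the rule for named genes and the alternatives, other than those said to be chosen later, were set before the data were examined. The rule named rraga, a panel of 14 genes, the 10 largest rises and 10 largest falls among changed genes with at least 10 CPM in the higher genotype, non-overlapping genotypes and an assigned symbol, the 3 members with the smallest p of each of the 18 lists, and the 2 most abundant members of each check list. Some genes that these rules picked are not reported here. Of the named genes, wipi1 and psmb8a overlap another gene holding at least 10% of their count, so their values are uncertain. The overlap of wipi1 is on its own strand, and those of psmb8a are on both strands. Paralogs such as cd74a with cd74b may share reads.

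Alternatives were median-of-ratios and upper-quartile factors, no filter, a filter of 5 CPM in 4 libraries, DESeq2, limma-voom with sample weights, glmTreat against a fold of 1.5, robust quasi-likelihood, replicate number as a block, each library left out, and markers of other cells left out. Scaling by library size alone and leaving out chromosome 14 were added after the data were seen.

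The procedure was tested on simulated counts for this comparison, with 200 of the genes changed. On 15676 simulated genes that passed the filter, edgeR's quasi-likelihood test recovered 0% of genes changed 1.5-fold, 16% at 2-fold, 56% at 4-fold and 78% at 8-fold. Among genes of at least 10 CPM it recovered 0%, 38.1%, 95% and 100%. The data held far more changed genes (2334 higher and 2233 lower), which makes the adjusted threshold easier to pass. These recoveries therefore do not give the share of changes missed in the data. Of the simulated calls, 3.85% were unchanged genes, and camera called 0 of 32 random lists. Simulated genes were drawn independently, so this does not test camera for lists whose members are correlated. Estimated correlations of the lists in the data ran from -0.0346 for endothelial markers to 0.871 for mitochondrially encoded genes. Lysosomal hydrolases had 0.274 and cytosolic ribosomal proteins 0.772. A first version of this simulation, in which fold and direction were tied, failed a requirement that 80% of all 8-fold genes be recovered, and after it was seen that the missed genes were of low abundance the requirement was restricted to genes of at least 10 CPM.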

Results

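Polyadenylated RNA was measured in cells of the macrophage lineage, which carried GFP under the mpeg promoter and were sorted by flow cytometry from zebrafish larvae of the TL strain at 6 days post fertilization. 4 libraries came from rraga mutants and 4 from wild-type siblings, numbered 1, 2, 4 and 5 in each genotype. rraga encodes RagA, a small GTPase that recruits mTORC1 to the lysosome in response to amino acids. The mutant libraries held 24940664 to 30911560 counts and the sibling libraries 25530526 to 29147340, assigned to 24221 genes, of which 16086 were tested.

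To determine how these cells differed between the genotypes, mutant libraries were compared with sibling libraries. More genes rose than fell among lysosomal hydrolases (36 and 2 of 64), V-ATPase subunits (17 and 0 of 21) and genes of the unfolded protein response (18 and 1 of 26). More fell than rose among markers of microglia (11 and 3 of 20), markers of the macrophage lineage (17 and 3 of 29) and cytosolic ribosomal proteins (70 and 1 of 78). These 6 lists passed the gene set test camera with its preset correlation, and none did with an estimated correlation (adjusted p from 0.197 to 0.524). lgmn, which encodes the lysosomal protease legumain, rose 9.58-fold, from 2992 ± 606 to 28650 ± 3326 CPM (SD, n = 4), and was the most abundant transcript in 3 mutant libraries. gpnmb, a glycoprotein gene activated by MiT/TFE transcription factors, rose 62.6-fold, from 71.6 ± 22.1 to 4477 ± 1252 CPM. p2ry12, a purinergic receptor gene typical of homeostatic microglia, fell from 88.0 ± 13.1 to 16.8 ± 3.77 CPM.

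With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at a threshold of 0.05, 2334 genes rose and 2233 fell, so that 51.1% of the changed genes were higher in mutants. A fold of at least 2 was reached by 1014 of the higher and 1248 of the lower genes, and a fold of at least 4 by 373 and 387. In 31.4% of the tested genes the 4 libraries of one genotype lay wholly above those of the other, where chance gives 2.86%. Scaled by library size alone, an alternative chosen after the data were seen, 1659 genes were higher and 3123 lower, or 34.7% higher. That scaling placed the median log2 fold change of all tested genes at -0.26, against -0.09 with TMM factors.

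rraga itself (ENSDARG00000104149, GRCz11 chromosome 14, 14027427 to 14094406) was higher in the mutants, at 199 ± 14.3 CPM against 129 ± 9.97 CPM in siblings (SD, n = 4). Its log2 fold change was 0.63 (SE 0.098, adjusted p = 0.00141 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An exact two-sided permutation test of the CPM values gave p = 0.0286, the smallest that 4 against 4 libraries allow. This test exchanges libraries freely and leaves out their pairing by column number. The labels do not give the allele, so the level of the transcript does not check the genotype. Against a minimum fold of 1.5 the difference did not pass (glmTreat, edgeR, adjusted p = 0.481).

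Genes for the transcription factors of lysosome biogenesis moved in opposite directions. tfeb rose by a log2 fold change of 1.38 (SE 0.174, 84.1 ± 12.7 against 32.3 ± 6.66 CPM), and tfe3a fell by 1.42 on the log2 scale (SE 0.143, 15.1 ± 1.82 against 40.4 ± 5.35 CPM). The adjusted p was 4.6e-04 for tfeb and 1.3e-04 for tfe3a (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). tfe3b, at 3.24 ± 1.03 against 2.48 ± 0.631 CPM, and mitfa, the melanocyte family member, at 8.11 ± 5.42 against 13.6 ± 6.73 CPM, did not pass the test. Neither did hmox1a, which encodes heme oxygenase, at 259 ± 31.5 against 277 ± 45.8 CPM. The raw counts were too low to test flcn (0 to 4 per library), slc7a7 (5 to 28) and ccl34b.1 (0 to 1).

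**Figure D1:**
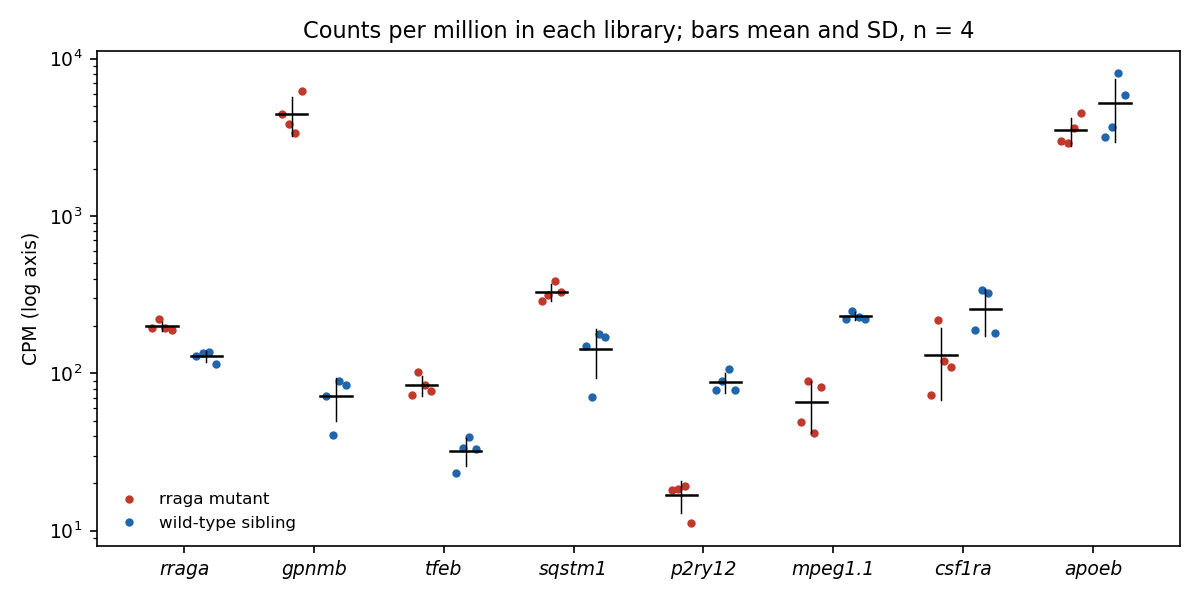
CPM (log axis) of 8 genes in each of the 4 rraga mutant (red) and 4 wild-type sibling (blue) libraries, with the mean and SD of each genotype as black bars. All mutant libraries lie above all sibling libraries for rraga, gpnmb, tfeb and sqstm1 and below them for p2ry12 and mpeg1.1, while the genotypes overlap for csf1ra and apoeb.

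More genes of the lysosome rose than fell. Of 64 tested lysosomal hydrolase genes 36 rose and 2 fell (39 and 3 adjusted over the list alone), and their transcripts made up 11.5% ± 1.2 of mutant counts against 5.08% ± 0.910 of sibling counts (SD, n = 4). Beside lgmn, ctsd for cathepsin D rose 8.22-fold (log2 fold change 3.04, SE 0.176), and gba for glucocerebrosidase rose 5.33-fold (log2 fold change 2.41, SE 0.144). Of 39 lysosomal membrane protein genes 16 rose and 1 fell (18 and 1 adjusted over the list alone), among them the lysosomal calcium channel gene mcoln1a (log2 fold change 2.07, SE 0.121), lamp2 (1.70, SE 0.146) and litaf (1.11, SE 0.0951). Of 21 V-ATPase subunit genes, whose products acidify the lysosome, 17 rose and 0 fell (17 and 0 adjusted over the list alone). These included tcirg1b (log2 fold change 1.49, SE 0.124), atp6v0ca (1.73, SE 0.158) and atp6v1c1a (1.08, SE 0.0953).

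All 3 lysosomal lists stood above the other genes by camera, with Benjamini-Hochberg adjustment over 32 lists. The hydrolases had adjusted p = 3.8e-16, and adjusted p = 0.316 with an estimated correlation. The membrane proteins had adjusted p = 8.9e-07, and adjusted p = 0.462 with an estimated correlation. The V-ATPase subunits had adjusted p = 1.9e-13, and adjusted p = 0.197 with an estimated correlation. Of the 13 lists past the camera threshold, 0 passed with an estimated correlation.

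Among 42 autophagy genes 14 rose and 4 fell (15 and 4 adjusted over the list alone). The ubiquitin-like gabarapa rose 5.08-fold and its conjugating enzyme gene atg3 2.16-fold, the phosphoinositide-binding wipi1 rose 2.23-fold, and sqstm1, the autophagy receptor p62, went from 142 ± 49.2 to 329 ± 41.9 CPM (log2 fold change 1.22, SE 0.257). The list did not pass camera (adjusted p = 0.0525, and adjusted p = 0.498 with an estimated correlation), and with the preset correlation it passed with replicate number as a block (adjusted p = 0.0367). It also passed without mutant library 1 (adjusted p = 0.0239), 4 (0.0321) or 5 (0.0357) and without sibling library 1 (0.0492), 2 (0.0241) or 4 (0.0414), with median-of-ratios factors (0.0407), without markers of other cells (0.0421) and without the filter on low counts (0.00556). Of 37 genes of Rag-mTORC1 nutrient sensing 11 rose and 2 fell (12 and 5 adjusted over the list alone). Among them rps6ka1, a ribosomal S6 kinase gene of the RSK family, stood at 58.5 ± 6.94 against 134 ± 10.9 CPM. It is distinct from the S6K genes rps6kb1a and rps6kb1b that were listed beside it. That list did not pass camera (adjusted p = 0.201).

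Genes of the unfolded protein response, chaperones as well as sensors and transcription factors, rose in 18 of 26 cases and fell in 1 (20 and 1 adjusted over the list alone). The calreticulin genes calr3b and calr3a rose 2.52-fold and 1.76-fold, and sdf2l1, for an endoplasmic reticulum chaperone cofactor, rose 2.21-fold. The list passed camera with adjusted p = 3.8e-07, and adjusted p = 0.462 with an estimated correlation. In the ATF4 amino acid response, 9 of 32 genes rose and 2 fell (10 and 3 adjusted over the list alone). The stress-induced nupr1 rose 16.6-fold, and the tryptophanyl-tRNA synthetase gene wars rose 2.70-fold, while trib3, a pseudokinase gene of the same response, fell by 0.71 on the log2 scale (SE 0.102). The list passed camera narrowly (adjusted p = 0.0410, and adjusted p = 0.316 with an estimated correlation). It did not pass with replicate number as a block (adjusted p = 0.0772), without mutant library 4 (0.0654), or without sibling library 2 (0.0617) or 5 (0.0553). Nor did it pass with upper-quartile factors (0.0604), scaled by library size alone (0.119) or with the stricter filter (0.250), and its median of 0.17 was as large as the shift that scaling by library size alone gave.

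More markers of microglia and of the macrophage lineage fell than rose. Of 20 microglia markers 11 fell and 3 rose (12 and 3 adjusted over the list alone), with a median log2 fold change of -1.12. havcr2, the checkpoint receptor gene TIM-3, fell by 2.85 on the log2 scale (SE 0.163), and lgals3bpb, a galectin-binding protein gene, by 1.81 (SE 0.122), while the transcriptional repressor gene bhlhe41 rose 8.15-fold, from 22.7 ± 1.54 to 185 ± 14.1 CPM. apoeb, an apolipoprotein gene abundant in microglia, stood at 3508 ± 720 against 5193 ± 2245 CPM and did not pass (adjusted p = 0.179, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera gave adjusted p = 1.8e-05 for the list, and adjusted p = 0.316 with an estimated correlation. slc7a7 and ccl34b.1, also listed as microglia markers, had too few counts to test even in siblings (6 to 28 and 0 to 1 per library). The share of microglia among the sorted cells was not measured.

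Of 29 macrophage lineage markers 17 fell and 3 rose (17 and 5 adjusted over the list alone). cd74a and cd74b, which encode the invariant chain of antigen presentation, fell by 3.30 (SE 0.138) and 3.36 (SE 0.141) on the log2 scale, and the immune checkpoint gene vsir fell by 2.04 (SE 0.126). mpeg1.1, the gene whose promoter drove the GFP used in the sort, went from 231 ± 13.2 to 65.5 ± 23.7 CPM. csf1ra, the receptor gene for the macrophage growth factor CSF1, was at 130 ± 62.6 against 257 ± 84.2 CPM. It did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0577), and it passed with replicate number as a block (adjusted p = 0.00354) and without mutant library 2 (0.0109), and by DESeq2, limma-voom, the stricter filter, upper-quartile factors and library sizes alone (adjusted p from 0.0261 to 0.0444). Camera gave adjusted p = 3.0e-06 for the lineage list, and adjusted p = 0.462 with an estimated correlation. Of 24 phagocytic and scavenger receptor genes 7 rose and 4 fell (8 and 5 adjusted over the list alone), and camera did not separate the list (adjusted p = 0.401). The bridging molecule gene mfge8a rose 7.68-fold and the engulfment gene dock1 3.51-fold, while the mannose receptor gene mrc1a fell by 2.90 on the log2 scale (SE 0.270).

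Beside these groups, transcripts induced by handling and transcripts of other cells also moved. Of 40 dissociation and immediate early genes 20 fell and 3 rose (23 and 3 adjusted over the list alone), and their share of counts was 1.02% ± 0.0917 in mutants against 1.86% ± 0.0713 in siblings. dusp1, a phosphatase gene of that list, fell by 1.57 on the log2 scale, and nfkbiab, the inhibitor of NF-kappaB, stood at 1734 ± 244 against 2017 ± 191 CPM and did not pass, except scaled by library size alone (adjusted p = 0.0394). The list passed camera with adjusted p = 1.9e-09, and adjusted p = 0.197 with an estimated correlation. Of 26 skeletal muscle markers 1 fell and 0 rose (0 and 0 adjusted over the list alone), and camera placed the list below the other genes (adjusted p = 0.00182, and adjusted p = 0.788 with an estimated correlation). Muscle transcripts took 0.510%, 0.0629%, 0.0865% and 0.304% of counts in mutant libraries 1, 2, 4 and 5, against 0.583% ± 0.0723 in siblings. With replicate number as a block the abundant muscle genes actc1b (log2 fold change -1.54, adjusted p = 0.0391) and mylz3 (-1.46, adjusted p = 0.0313) passed edgeR's quasi-likelihood test, which they did not pass without it (adjusted p = 0.251 and 0.229), although they did without mutant library 1 (0.0277 and 0.0292).

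Of 26 epithelial and keratinocyte markers 8 fell and 1 rose (10 and 1 adjusted over the list alone), and camera placed them lower (adjusted p = 0.0174, and adjusted p = 0.788 with an estimated correlation). That call was lost without mutant library 2 (adjusted p = 0.129). anxa1a, the annexin gene of that list, rose 5.25-fold, and the calcium-binding icn stood at 256 ± 149 against 321 ± 71.0 CPM. No further list of another cell type passed camera. The counts of higher and lower genes were 2 and 3 of 13 for neutrophils (adjusted p = 0.811), 1 and 3 of 11 for lymphoid cells (0.213), 2 and 1 of 14 for erythroid cells (0.817), 0 and 2 of 27 for neurons (0.109) and 1 and 2 of 14 for glia (0.588). They were 0 and 3 of 23 for photoreceptors and lens (0.0605), 1 and 8 of 41 for liver, pancreas and gut (0.146), 4 and 2 of 13 for endothelium (0.745), 3 and 0 of 20 for pigment cells (0.201) and 1 and 1 of 19 for fibroblasts and cartilage (0.281). Adjusted over the list alone, the higher and lower genes numbered 2 and 3 for neutrophils, 1 and 4 for lymphoid cells, 2 and 1 for erythroid cells, 0 and 1 for neurons, 1 and 2 for glia, 0 and 2 for photoreceptors and lens, 1 and 2 for liver, pancreas and gut, 4 and 3 for endothelium, 3 and 0 for pigment cells and 0 and 1 for fibroblasts and cartilage. The endothelial list had a negative median and a positive mean and test direction. The myeloid factor gene cebpa, listed with neutrophils, rose 2.39-fold, and the endothelial ramp2 rose 3.74-fold.

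**Figure D2:**
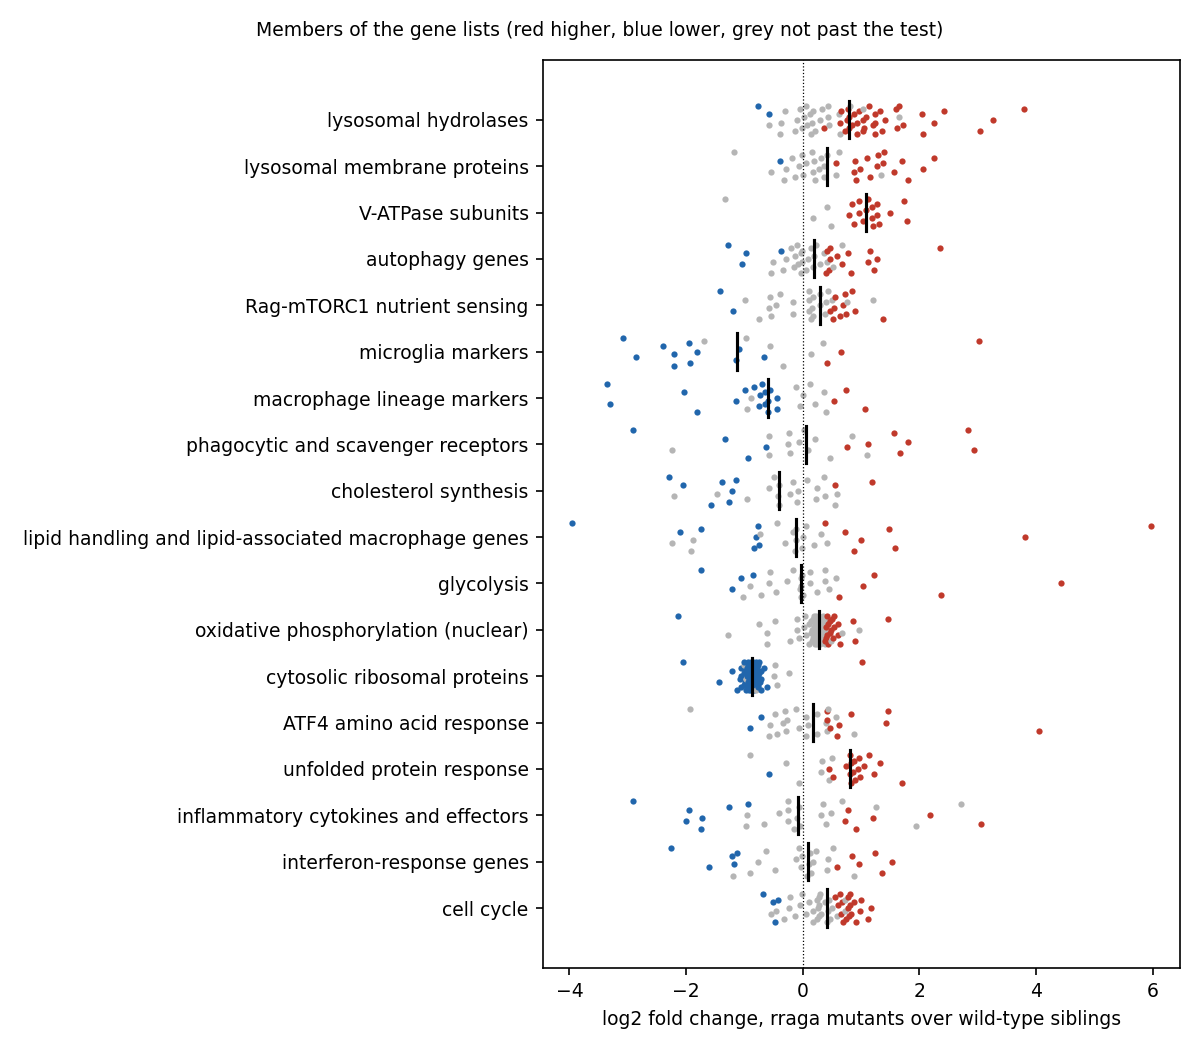
Log2 fold change (mutants over siblings) of each tested member of 18 gene lists, with the list median as a black line; red members rose and blue members fell by edgeR's quasi-likelihood test, and grey members did not pass. The V-ATPase median lies at 1.08, the microglia marker median at -1.12 and the ribosomal protein median at -0.87.

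Ribosomal protein transcripts fell nearly as a block. Of 78 tested genes 70 fell and 1 rose (73 and 1 adjusted over the list alone), with a median log2 fold change of -0.87, and their share of counts was 1.98% ± 0.333 in mutants against 3.95% ± 0.648 in siblings. rpl4 fell by 0.90 (SE 0.135) on the log2 scale, while the gene named rpl26 in the deposited data rose 2.03-fold. Another gene of that name overlaps it on the same strand. A reference source of gene names matched atp6v0e1, a V-ATPase subunit gene, to a gene named rpl26. The deposited name was kept, so the identity of this gene is uncertain. Among the 32 lists this one had the smallest camera result, adjusted p = 5.3e-17, and adjusted p = 0.524 with an estimated correlation. Among 86 nuclear genes of oxidative phosphorylation 20 rose and 1 fell (20 and 1 adjusted over the list alone), with ndufa10 of complex I 1.87-fold and uqcrfs1 of complex III 1.56-fold higher, and with cox8b of complex IV lower by a log2 fold change of -2.13. This list passed camera with adjusted p = 9.5e-04, and adjusted p = 0.788 with an estimated correlation. The 13 mitochondrially encoded genes held 0 that rose and 0 that fell (0 and 0 adjusted over the list alone), and camera did not separate them (adjusted p = 0.236), although the list passed without mutant library 1 (adjusted p = 0.00381). The complex IV gene mt-co2 went from 3979 ± 523 to 2748 ± 965 CPM, which passed edgeR's quasi-likelihood test only with replicate number as a block (adjusted p = 0.0441), scaled by library size alone (0.0336) or without mutant library 1 (0.00584).

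Other metabolic lists held members that moved both ways. In glycolysis 5 of 30 genes rose and 4 fell (8 and 5 adjusted over the list alone), with aldocb, an aldolase gene, 5.16-fold higher and gapdh lower by a log2 fold change of -1.75. Its median was negative and its mean and camera direction were positive (adjusted p = 0.817). Of 28 cholesterol synthesis genes 7 fell and 2 rose (7 and 3 adjusted over the list alone), and camera gave adjusted p = 0.213. The sterol demethylase gene cyp51 fell by 1.58 on the log2 scale, nsdhl by 2.29 and hsd17b7 by 1.27. Of 31 genes of lipid handling and lipid-associated macrophages 8 rose and 7 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.990), and the paralogous tetraspanin genes cd9b and cd9a fell by 1.74 and rose by a log2 fold change of 1.58.

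Cell cycle genes rose in 19 of 52 cases and fell in 4 (20 and 5 adjusted over the list alone). The mitotic cyclin gene ccnb1 rose 1.98-fold, CKS2 for a cyclin-dependent kinase subunit 2.24-fold and the spindle midzone gene prc1b 1.71-fold. The 4 members that fell were mcm2, mcm3, mcm4 and mcm6, which encode subunits of the replicative helicase and were singled out after their values were seen. By camera the cell cycle list had adjusted p = 0.00182, and adjusted p = 0.788 with an estimated correlation. Of 32 inflammatory genes 6 rose and 7 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.745), with a negative median and a positive mean. The chemokine genes ccl38.1 and ccl35.1 fell by 2.91 and 1.72 on the log2 scale, and csf3a, for a granulocyte growth factor, by 1.96. Of 30 interferon-response genes 6 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.824), with a positive median and a negative mean. gbp1, a guanylate-binding protein gene, rose 2.58-fold and the transcription factor gene irf7 fell by 1.18, while psmb8a, an immunoproteasome gene higher by a log2 fold change of 1.24, overlaps its neighbours psmb12 and psmb9a on the other strand and psmb13a on its own.

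The largest rises by fold, among genes of at least 10 CPM, were of tex2l, gda, helt, trim35-10, calcoco1b, twf2a, ankrd6a, gpnmb, cobll1a and mmp25b. gda, a guanine deaminase gene, went from 11.9 ± 2.44 to 2069 ± 300 CPM, and mmp25b, a membrane-bound metalloproteinase gene, from 16.5 ± 1.89 to 872 ± 55.5 CPM. Among the 10 largest falls, g0s2, an inhibitor of triglyceride lipolysis, went from 1082 ± 349 to 63.4 ± 15.8 CPM, csad, for taurine synthesis, from 24.2 ± 9.32 to 0.610 ± 0.313 CPM, and hbegfb, an EGF-family ligand gene, from 71.0 ± 31.0 to 6.26 ± 0.878 CPM. fam198b and the transcription factor gene mafaa were also among them. chia.1, a chitinase gene, passed with all libraries (adjusted p = 0.0437, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and was lost without any library except mutant 4 (adjusted p from 0.0520 to 0.0953) and by the robust fit (0.0741).

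Of the other largest falls, hdac3, tmsb1 and hspa9 lie in one interval on chromosome 14, 1.82 Mb from rraga. Between 12020936 and 12205865 all 6 tested genes fell, among them zgc:66447 and prps1b, which were named after their values were seen. hdac3, for a histone deacetylase, had 1 to 4 counts per mutant library and 12.1 ± 10.6 CPM in siblings, and hspa9, for the mitochondrial chaperone mortalin, went from 54.4 ± 38.8 to 4.33 ± 0.946 CPM. tmsb1, a thymosin gene, went from 106 ± 77.5 to 1.12 ± 1.16 CPM. By limma-voom, hdac3 did not pass (adjusted p = 0.0920). The genes sqstm1, tcirg1b, lamp2, cd74a, csf1ra, nsdhl, dusp1, fam198b and rpl26 also lie on chromosome 14. Of these, nsdhl, dusp1, sqstm1 and tcirg1b lie within 5 Mb of rraga.

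**Figure D3:**
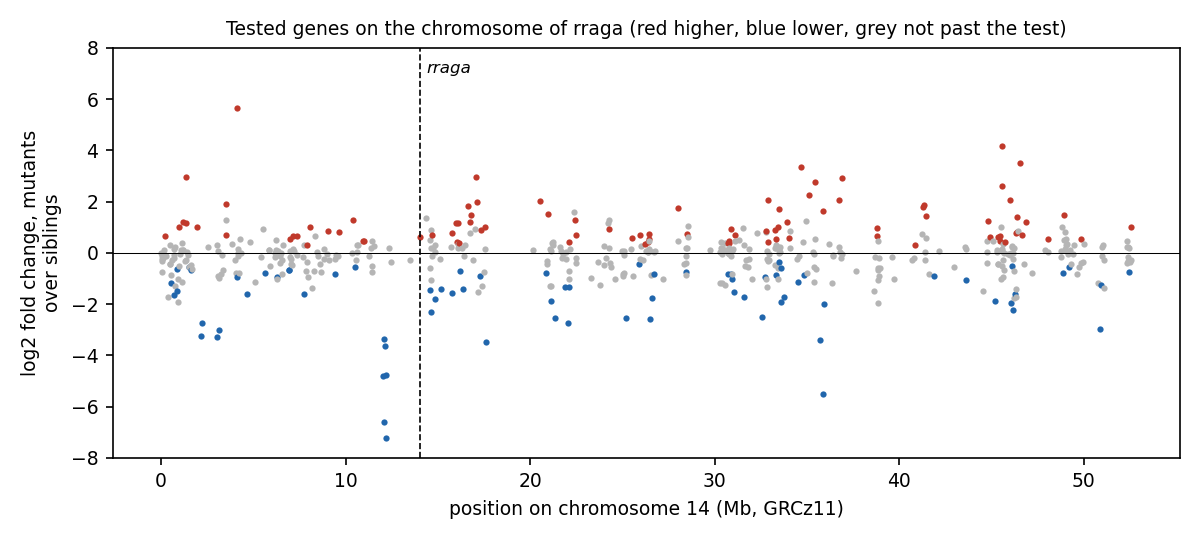
Log2 fold change (mutants over siblings) of tested genes against position on chromosome 14 (Mb, GRCz11), with rraga at the dashed line; red genes rose, blue genes fell and grey genes did not pass edgeR's quasi-likelihood test. The 6 neighbouring genes near 12 Mb lie between -3.35 and -7.22.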

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

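Tests of the split of libraries, of the whole of chromosome 14 and of length bias were set out before their results were seen, and the other tests in this part were chosen only after the result was seen. In groups of 4 libraries, a library was taken as far from the others where its gap to the nearest, as a share of the range, exceeded Dixon's 95% critical value. Of 284 groups examined, 12 met this, and chance gives about 14.2 (1 in 20).

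Among genes, the gap as a share of the range was 0.901 for p2ry12 in mutant library 5, 0.961 for twf2a and 0.851 for ankrd6a in mutant 2, and 0.883 for mafaa in mutant 2. It was 0.939 for havcr2 in sibling 4, 0.865 for mfge8a in mutant 4, 0.906 for aldocb in sibling 2, 0.852 for trib3 in mutant 1 and 0.832 for mt-co2 in mutant 1. Among shares of counts it was 0.879 for Rag-mTORC1 genes and 0.892 for phagocytic receptors in sibling 2, and 0.844 for neuronal markers in mutant 5.

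Regrouping the 8 libraries did not give the number of changed genes. Of 35 splits into 4 and 4, only 1, the split by genotype, reached 4567 genes by edgeR's quasi-likelihood test, and the highest other split gave 9. Over these 35 splits the share that reached this count is under 0.05, but they include splits that do not part the numbered pairs. The 8 splits that part all 4 numbered pairs are too few for a share under 0.05, and the highest other of these gave 0 genes. With the pairing, this test therefore cannot exclude chance.

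Macrophage lineage and microglia transcripts were lower in mutants. If cells of all other types had been more frequent alike in the mutant sorts, their markers would have been higher together, but 1 of 12 lists of other cell types had a median log2 fold change above 0. The muscle share was 0.241% ± 0.210 against 0.583% ± 0.0723, without overlap of the genotypes (exact permutation test without the pairing, adjusted p = 0.0831 over 32 lists). Each list without overlap had this same value, lysosomal hydrolases among them, and no list had a smaller one. By share of counts 5 of the 12 were higher in mutants, those of neutrophils, lymphoid cells, glia, endothelium and pigment cells. Without the most abundant member of each list (cebpa, ccr9a, glula, ramp2 and gpnmb) only 1 of these stayed higher, that of pigment cells, at 0.319% ± 0.331 against 0.284% ± 0.195. Mutant library 5 weighs on that value. The pigment gene tyrp1b had 2920 CPM there, and 152 to 888 CPM in the other mutant libraries. Without mutant library 5 its log2 fold change was -1.09. The other members of the neutrophil, lymphoid, glial and endothelial lists thus lend no support to a gain of those cells, and a gain of pigment cells or of a type without a list stays open. A uniform loss of the cells that carry these transcripts would not by itself raise members, and 12.2% of the 49 members, or 6 genes, rose. However, 2334 of all 16086 tested genes rose, so the 6 may share in that wider change. A loss of cells behind the falls therefore stays open. The median of the 49 members lay -0.58 from that of all tested genes, more than 3 times the largest shift between scalings (0.171). A change of scaling moves both medians about alike, so this comparison cannot test an effect of scaling. The distance shows only that these members lay below the other tested genes. A changed expression program and a changed mix of cell states within the sorted lineage remain open and were not separated, and genotype is a candidate explanation for either.

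Ribosomal protein transcripts were lower in mutants. The list median lay at percentile 0 of 10000 random lists matched on gene length and abundance, whose lowest median was -0.15, which argues against a bias of length or abundance. The distance of -0.78 from the median of all tested genes exceeds what scaling shifted. Scaling moves both medians about alike, so that comparison does not test scaling and shows only a fall relative to the other genes. The dissociation and immediate early genes were lower in mutants as well (1.02% ± 0.0917 against 1.86% ± 0.0713 of counts, camera adjusted p = 1.9e-09, and adjusted p = 0.197 with an estimated correlation). Counts on rRNA genes were 0.893% ± 0.450 in mutants against 1.44% ± 0.336 in siblings, with overlap of the genotypes, and genes with a count numbered 20160 ± 666 against 21092 ± 309, also with overlap. Within each numbered pair the mutant library had fewer genes with a count than the sibling library. A difference in sorting or RNA handling between the genotypes therefore stays open for this fall and for that of the macrophage lineage and microglia transcripts, beside an effect of genotype.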

How the results depend on the processing

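Scaling by library size alone and the fit without chromosome 14 were chosen after the data were seen. No called gene or list changed sign under any alternative. Higher genes numbered 1659 to 2860 and lower genes 1671 to 3123 under every alternative except glmTreat against a fold of 1.5, which called 861 higher and 742 lower genes and left rraga, at a log2 fold change of 0.63, short of the threshold; that test asks for a larger fold by construction. It also left out sqstm1 (adjusted p = 0.0520), rpl4 (0.0536), hsd17b7 (0.0537), calr3a (0.0747), chia.1 (0.101), prc1b (0.121), trib3 (0.213) and uqcrfs1 (0.459). With single libraries left out, 1919 to 2203 genes were higher and 1671 to 2093 lower. With an estimated correlation, camera gave adjusted p = 0.316 for lysosomal hydrolases, 0.462 for lysosomal membrane proteins, 0.197 for V-ATPase subunits and 0.316 for microglia markers, and 0 of 32 lists passed, against 13 with the preset correlation; 5 had an unadjusted p under 0.05. By fry, which tests a list against no change and not against the other genes, 13 lists passed, without those of oxidative phosphorylation (adjusted p = 0.0730), cell cycle (0.0536), skeletal muscle (0.0947) and epithelium (0.0676) and with those of autophagy (0.00379), Rag-mTORC1 nutrient sensing (0.00991), cholesterol synthesis (0.0237) and lymphoid cells (0.0110). The replicate block gave 2857 higher and 2673 lower genes and changed no call of a named gene or list other than those of csf1ra, mt-co2, actc1b, mylz3, the autophagy list and the ATF4 list. Without chromosome 14, 2249 genes were higher and 2154 lower, and 13 lists passed. That fit does not remove any effect that changed genes of chromosome 14 may have on genes elsewhere. Among lists that missed the test, photoreceptor and lens (adjusted p = 0.00574), neuronal (0.0471) and fibroblast markers (0.0193) passed as lower without mutant library 1, photoreceptor and lens (0.00550) and neuronal markers (0.0152) without sibling 1, photoreceptor and lens markers without sibling 5 (0.0444) or with median-of-ratios factors (0.0407), and photoreceptor and lens (0.0321) and liver, pancreas and gut markers (0.00144) without mutant 4, when pigment markers passed as higher (0.0310); the cause was not tested. The alternative for a table without counts was not run because the table holds counts. In the simulation, which held far fewer changed genes than the data, small folds and genes of low abundance were often missed.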

Other observations

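The tests in this part were chosen only after the result was seen, except that of the whole of chromosome 14. Genes were also grouped by the stem of their symbol, which gave 108 families of at least 12 tested members. Proteasome genes rose: 11 of 12 psmb genes, for the proteolytic core ring, and 15 of 16 psmd genes, for the regulatory particle, with medians of 0.82 and 0.64. Camera gave adjusted p = 5.3e-06 for each, and adjusted p = 0.492 with an estimated correlation. Of 33 vps genes 14 rose and of 13 trappc genes 10 rose, with 0 lower in both families (camera adjusted p = 3.1e-05 and 0.00107, and adjusted p = 0.492 with an estimated correlation for both). Among 60 rab genes, for GTPases of membrane traffic, 18 rose and 4 fell (camera adjusted p = 0.0242, and adjusted p = 0.492 with an estimated correlation). The snx family held 11 of 32 genes that rose and 5 that fell (camera adjusted p = 0.00499, and adjusted p = 0.547 with an estimated correlation), and the sec family 5 of 23 that rose and 4 that fell (camera adjusted p = 0.712, and adjusted p = 0.907 with an estimated correlation). The stx and atp families also passed camera as higher (adjusted p = 0.00947 and 0.00405, and adjusted p = 0.492 with an estimated correlation for both). By its stem the atp family includes V-ATPase and oxidative phosphorylation genes already tested in those lists, so it is not a separate result.

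Of 15 tlr genes, for toll-like receptors, 8 fell and 1 rose, with a median log2 fold change of -1.37. Camera gave adjusted p = 0.0188, and adjusted p = 0.492 with an estimated correlation.

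The 6 neighbouring genes on chromosome 14 form the longest run of adjacent tested genes with a fall of at least 4-fold, and the next longest run held 3. The longest run in 10000 shuffles of gene order held 5, a share of 0.0001 and the smallest they can give. Sibling library 2 had the highest and sibling library 5 the lowest level of all 6 genes, with ratios between them of 5.71 to 17.7, and 0.0127% of other runs of 6 adjacent genes shared both extremes. A haplotype over this interval that is linked to the mutation, poorly matched by the reference or lacking these genes, and held in different shares by the sibling libraries may account for both values, as a hypothesis found in these counts. Shared regulation of the interval predicts the same values and stays open, since no sequence was analysed here.

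On chromosome 14 as a whole, 31.1% of 534 tested genes changed, against 28.3% of other genes (odds ratio 1.14, 95% interval 0.943 to 1.38, Fisher's exact test, two-sided). Changes of at least 4-fold were more frequent there, at 6.74% against 4.66% (odds ratio 1.48, 95% interval 1.017 to 2.098), and without the 6 neighbouring genes the odds ratio was 1.23 (95% interval 0.817 to 1.80). The bound set beforehand, an upper limit of 1.5 for all changed genes, was met, but it weighs small changes as much as large ones, so linked strain differences on this chromosome stay open. Within 2.5 Mb of rraga 19 of 39 genes changed (odds ratio 2.41, 95% interval 1.21 to 4.76), but this window holds the 6 neighbouring genes, and without them 13 of 33 did (odds ratio 1.65, 95% interval 0.752 to 3.48). From 2.5 to 5 Mb 15 of 37 genes changed (odds ratio 1.73, 95% interval 0.833 to 3.49). From 5 to 10 Mb 25 of 101 did (odds ratio 0.834, 95% interval 0.51 to 1.33), and farther away the odds ratios were 1.12 and 1.05. Both windows nearest to rraga thus had a higher share, with intervals that include 1 once the 6 genes are left out. Of 76 genes within 5 Mb, 46.1% varied more among siblings than among mutants, against 46.5% of other genes (odds ratio 0.984, 95% interval 0.608 to 1.59), and the interval is too wide to exclude a mix of haplotypes there.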
